A study of Mus musculus with 4 samples.

How the data were processed

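Total RNA from spleen CD4+ T cells, cultured for 3 days under Tfh conditions with or without DMF, was sequenced on an Illumina HiSeq2000, per the labels. Both groups, control and DMF, hold 2 libraries. Nothing in the labels says that the replicates came from separate cultures or animals. The p-values of single genes therefore measure only the spread between these samples, which may be technical. Those of limma's camera compare a list's genes with other genes in these same samples. The DMF libraries differed by more than counting error alone (chi-square per degree of freedom 3.79 over genes with at least 20 reads, against 179 for the controls) and were kept as 2 samples.

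The authors deposited 1 table of FPKM values for 54532 genes with gene names, coordinates and lengths, per the file headers. The aligner and the counting program are not given in the sources used here. The submitters' processing notes name edgeR, without its role, and the genome build mm8. Of the 54409 gene identifiers found in the GENCODE M21 annotation (GRCm38), 98.33% have the same chromosome, start and end in the deposited table, so coordinates are given as GRCm38. Every column that holds a library's values was used.

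FPKM multiplied by gene length gave whole multiples of 1 step in each library for 100% of the values, within 0.01, so reads per gene could be worked out. These reads, of which at least 99.13% per library fall in the tested genes, sum to 17171199, 15900118, 17134385 and 17516953 in control replicates 1 and 2 and DMF replicates 1 and 2. The deposited FPKM imply library sizes of 17725674, 13929627, 18302380 and 18672223 reads, so the authors' scaling differed from the read total by a factor of 1.032, 0.876, 1.068 and 1.066. A gene with 0 reads in a library is compatible with up to 3 reads there, for counting error only.

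The main test was limma 3.58.1 (lmFit, then eBayes with a trend in mean expression) in R 4.3.3 on log2(FPKM + 1), two-sided, DMF minus control, with no covariate. It covered the 12166 genes with a mean FPKM of at least 1 over the 4 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 fold change on this scale understates the change of genes with low values. The deposited unit is FPKM, so the main test was no count test. A planned pair of count tests on recovered reads was not run, and limma's voom took its place. Gene lists, 23 in number, were fixed before the data were examined. They were tested with limma's camera at a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 21 lists with at least 5 tested members. camera with an estimated correlation and fry were run beside it. fry asks whether a list's genes move, on balance, one way, or, in its mixed form, in either direction, and compares no list with other genes. The variance trend used by camera was set after camera without it had been run, and both forms called 11 lists. Some lists share genes, such as Tcf7 and Lef1 in the Tfh and naive lists.

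Genes were named by a rule set before the data were examined. It takes 10 fixed genes, the genes past the threshold with the largest changes or, with none past it, the 5 with the smallest p in each direction, leaving out predicted genes, pseudogenes, receptor segments and small RNAs. It also takes up to 4 members of each list with the smallest p. Further list members are named as examples chosen after their values were seen. Some genes that the rule takes are not reported here. Gene names come from the deposited table. Reads of near-identical or overlapping genes, such as Hspa1a and Hspa1b, Tgtp1 and Tgtp2, or Igtp and Irgm2, may be split or shared by the counting, and values of these genes are uncertain.

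The scripts were tested on simulated reads of the real genes with 200 genes changed. With equal libraries the main test called 88% of 2-fold and 99% of 4-fold changes, with 13 false calls among 12187 genes. With 1 control given the gene length trend and scatter of control replicate 2, it called 0% of both, and leaving that control out called 93% and 100% with 91 false calls among 12205 genes. In simulated lists of 20 unchanged genes, 2.5% had p under 0.05 with the preset correlation and 0% with an estimated one. Apart from the length trend the simulated genes varied independently. These shares therefore do not give the rate of false calls for lists of genes that vary together.

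The alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a mean FPKM of at least 5, a trimmed mean of log ratios as scaling (written out, trimming 30% of ratios and 5% of levels at each end), quantile normalization, eBayes without a trend and in its robust form, a log2 change of at least 1, the replicate number as a block, and each library left out in turn. Chosen after the data were seen were limma's voom on the recovered reads, library quality weights, removal of a gene length trend and of a GC trend (loess, span 0.3, GC known for 99.9% of tested genes), camera without a variance trend, and 3 more gene lists, tested with at least 2 members. Benjamini-Hochberg adjustment of these 3 lists ran over them alone. Further tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.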

Results

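The data were RNA-seq libraries of mouse CD4+ T cells from the spleen. Naive CD4+ T cells were cultured for 3 days under conditions that direct them to T follicular helper (Tfh) cells, the T cells that help B cells make antibody. The cultures held dimethyl fumarate (DMF), a fumaric acid ester that activates the transcription factor Nrf2, or none. The 4 libraries form 2 groups, control and DMF, with 2 libraries each, all from wild-type mice. The files give FPKM (fragments per kilobase of gene, scaled to library size), from which whole reads per gene were worked out. They come to 17171199 reads in control replicate 1, 15900118 in control replicate 2, 17134385 in DMF replicate 1 and 17516953 in DMF replicate 2. The series title ties DMF to chronic graft-versus-host disease, Tfh differentiation and Nrf2, so the comparison asks what DMF does to the transcripts of cells under Tfh conditions.

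DMF cultures held less RNA of most tested cytokine signal feedback genes, naive T cell genes and Th1 genes than control cultures. They held more RNA of most tested B cell marker, cell cycle and amino acid stress response genes. The lists of STAT-induced feedback genes, Th1 genes and naive T cell genes fell (limma camera, preset correlation), with medians of -1.26, -1.14 and -0.90 on the log2 scale. Each had an adjusted p of 0.216 with an estimated correlation. The B cell, cell cycle and stress response lists rose with the preset correlation and had adjusted p of 0.216, 0.36 and 0.56 with an estimated one. None of these 3 passed without control replicate 1, where their medians were 0.65, 0.291 and 0.106, nor did the naive T cell list, with a median of -1.02. Ighm, an abundant B cell transcript, was lower in both DMF libraries than in both controls. In limma's fry the cell cycle and stress response lists did not pass (adjusted p = 0.105 and 0.228). Gzmb, which encodes the cytotoxic protease granzyme B, was at 115 ± 23.3 FPKM in control and 5.48 ± 0.482 in DMF cultures (SD, n = 2), a ratio of 20.9. CD8 T and NK cells also express Gzmb, and the 3 tested markers of these cells were lower too, with a ratio of 23.4 for Cd8a. Transcripts of Nfe2l2, which encodes Nrf2, were at 12.5 ± 0.688 FPKM in control and 12.4 ± 0.518 in DMF cultures (SD, n = 2), which does not measure the activity of the Nrf2 protein. Of 23 tested Nrf2 targets, 9 lay above both controls in both DMF libraries, among them Hmox1, Gclc, Txnrd1 and Srxn1, and 7 lay below both. The target list did not pass (camera adjusted p = 0.653). Its median of -0.17 was -0.27 without control replicate 1 and 0.167 without control replicate 2. Under quantile normalization that median was 0.212, with a camera adjusted p of 0.0403. Genes of the Tfh program lay in both directions, with Bcl6 and Pdcd1 higher and Il21 lower in the DMF libraries.

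Over single genes limma called 0 of the 12166 tested at an adjusted p under 0.05 (lowest adjusted p = 0.128), against 1150 genes at an unadjusted p under 0.05, where chance gives 608. Of these 1150 genes, 382 were higher and 768 lower in the DMF libraries. limma's voom on the recovered reads also called 0 genes, with 1168 at an unadjusted p under 0.05. In simulated reads with 1 control like control replicate 2, voom and the main test each called 0% of 2-fold and of 4-fold changes. The 0 calls therefore do not show that no gene changed. Both DMF libraries lay above both controls or below both in 53.2% of the genes, where chance gives 33.3% if the 4 libraries are exchangeable. The controls lay further apart than the DMF libraries, which can raise the share that chance gives. Among these, 203 were higher and 487 lower by at least 1 on the log2 scale. The count moved with each library left out: 1007 genes passed without control replicate 2, 7420 without control replicate 1, 8 without DMF replicate 1 and 6 without DMF replicate 2.

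Control replicate 2 stood apart from the other 3 libraries. The SD of the log2 difference between the controls was 0.74 over genes, against 0.32 between the DMF libraries and 0.46 and 0.45 between control replicate 1 and the DMF libraries. Genes for ribosomal proteins took 14.67% of the reads of control replicate 2, and 7.36%, 6.73% and 6.73% in control replicate 1, DMF replicate 1 and DMF replicate 2. Its distance from the other libraries fell with gene length past the shortest genes, from a median of 0.75 in genes of 580 to 1444 bp to -0.63 in genes of 8933 to 40491 bp, which are group 2 and group 10 of 10 groups of similar size by length. Group 1, of 11 to 579 bp, broke the trend with a median of -0.04.

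**Figure D1:**
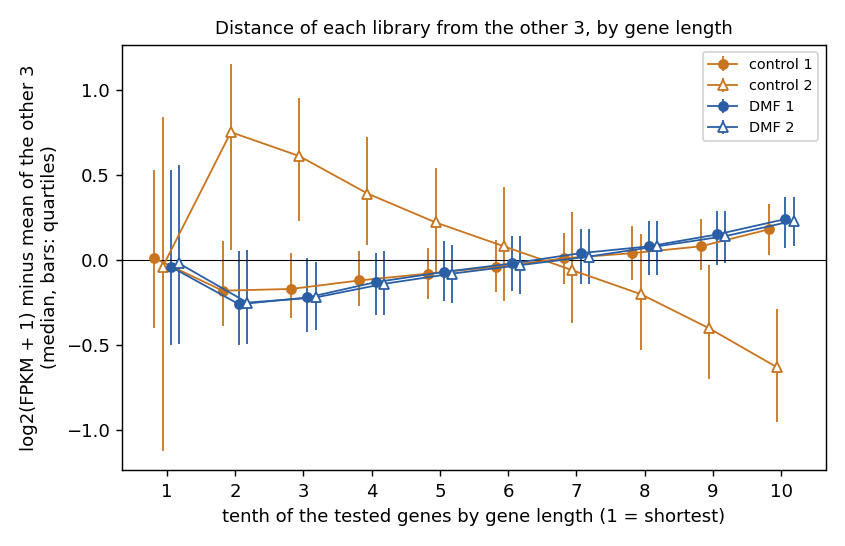
The distance of each library's log2(FPKM + 1) from the mean of the other 3 (y axis; median, with bars from the lower to the upper quartile) is plotted for 10 groups of tested genes by gene length (x axis, 1 holds the shortest genes). Control replicate 2 lies at -0.04 in group 1 and goes from 0.75 in group 2 to -0.63 in group 10, and the other 3 libraries lie between -0.26 and 0.24.

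For Nrf2, a transcription factor that drives antioxidant genes, the gene itself and a list of 30 target genes were examined. Nfe2l2 (ENSMUSG00000015839, protein coding, GRCm38 chromosome 2, 75675513 to 75704641) differed by -0.01 ± 0.17 on the log2 scale (SE, n = 2 per group). Its inhibitor Keap1 was at 21.8 ± 0.532 FPKM in control and 19.2 ± 0.451 in DMF cultures (SD, n = 2). Hmox1 (GRCm38 chromosome 8, 75093621 to 75100589), which encodes the heme-degrading enzyme heme oxygenase 1, was at 8.82 ± 2.31 FPKM in control and 13.6 ± 0.201 in DMF cultures (limma adjusted p = 0.536). Gclc, which encodes the catalytic subunit of the first enzyme of glutathione synthesis, was at 7.7 ± 2.24 and 14.8 ± 0.806 FPKM. Txnrd1, a thioredoxin reductase, was at 23.1 ± 4.03 and 39.3 ± 1.11 FPKM, and Srxn1, a sulfiredoxin, at 1.82 ± 0.373 and 3.5 ± 0.646 FPKM. Nqo1, a quinone reductase, lay below the level filter, with 13 and 8 reads in the controls and 36 and 39 reads in the DMF libraries, a ratio of 3.1 in FPKM. In all, 9 of the 23 target genes tested lay above both controls in both DMF libraries and 7 lay below both. No member passed, over all genes or adjusted over the list alone. The list did not pass either (camera adjusted p = 0.653), and its median of -0.17, mean of 0.01 and test direction (up) differed in sign. The median was -0.27 without control replicate 1. Without control replicate 2 it was 0.167 with an adjusted p of 0.0231, under quantile normalization it was 0.212 with an adjusted p of 0.0403, and over 17 alternatives the adjusted p ran from 0.0231 to 0.836.

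The 24 genes of the Tfh program, of which 22 were tested, did not move as 1 group (median 0.14, camera adjusted p = 0.332), and the median was 0.0633 without control replicate 2 and 0.27 without control replicate 1. Bcl6 (GRCm38 chromosome 16, 23965052 to 23988852), which encodes the transcription factor that sets the Tfh fate, was at 3.89 ± 0.927 FPKM in control and 6.67 ± 0.123 in DMF cultures (SD, n = 2), a difference of 0.66 ± 0.21 on the log2 scale (SE, limma adjusted p = 0.496). Cxcr5, the receptor that guides T cells to B cell follicles, was at 1.06 ± 0.101 and 1.93 ± 0.165 FPKM, and Pdcd1, which encodes PD-1, at 90.5 ± 13.8 and 138 ± 2.89 FPKM. B cells, whose markers were also higher in the DMF libraries, express Bcl6 and Cxcr5 too. In the other direction, Il21 (GRCm38 chromosome 3, 37222759 to 37232636), the cytokine by which Tfh cells act on B cells, was at 28.3 ± 3.97 FPKM in control and 9.97 ± 1.13 in DMF cultures (-1.42 ± 0.20 on the log2 scale, adjusted p = 0.201). Icos, a costimulatory receptor, was at 49.6 ± 0.902 and 36.4 ± 0.668 FPKM. Maf, a transcription factor that drives Il21, was higher in DMF cultures, at 9.67 ± 1.35 against 3.68 ± 1.31 FPKM. Adjusted over the list alone, Angptl2, Tox, Maf and Pou2af1 rose and Il21 fell. Prdm1, which encodes Blimp-1, the antagonist of Bcl6, was below the filter, at 0.0685 ± 0.0605 FPKM in control and 0.302 ± 0.141 in DMF cultures. Under quantile normalization the list's median was 0.422 with an adjusted p of 0.0409 (0.0409 to 0.604 over 17 alternatives).

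**Figure D2:**
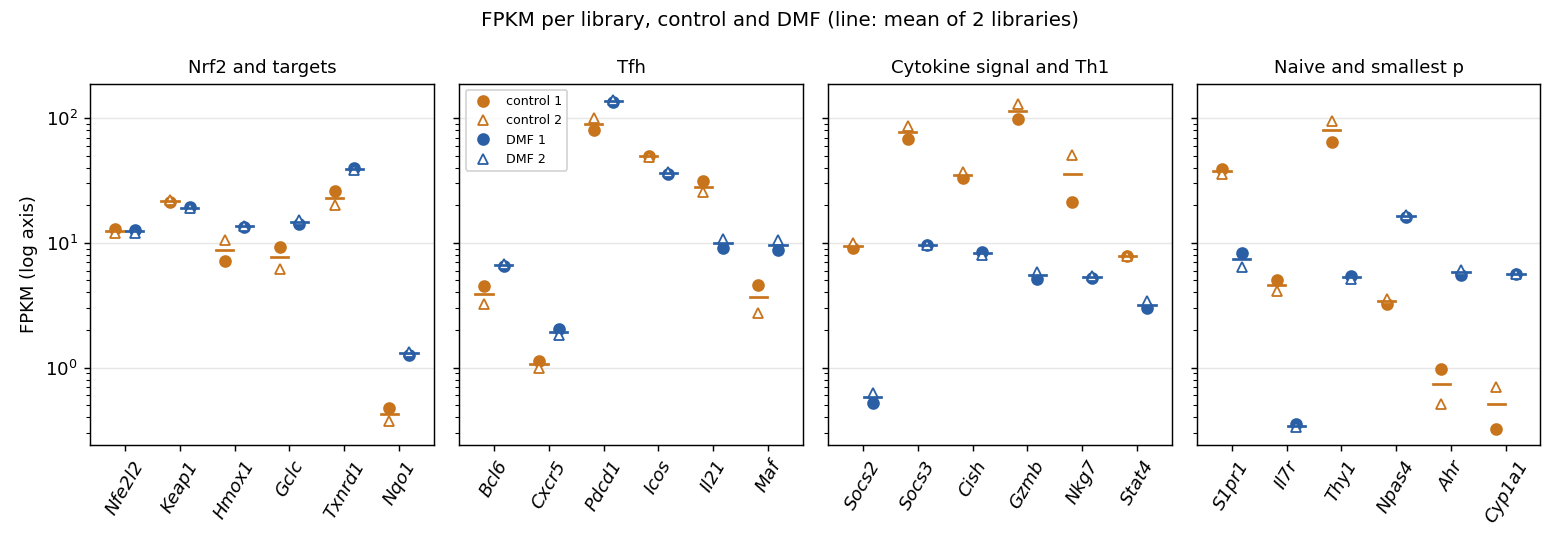
FPKM (y axis, log scale) of 24 named genes in each library, with the mean of the 2 libraries of each group as a line. Control libraries are orange and DMF libraries blue, with replicate 1 filled and replicate 2 open. Nfe2l2 lay at 12.9 and 12 FPKM in the controls and 12.8 and 12 in the DMF libraries, while Gzmb lay at 98.1 and 131 in the controls and 5.14 and 5.82 in the DMF libraries.

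With no gene past the threshold, the 5 genes with the smallest unadjusted p in each direction were taken as the rule set beforehand asks. Higher in the DMF libraries were Npas4, an activity-dependent transcription factor (3.39 ± 0.221 FPKM in control and 16.4 ± 0.398 in DMF cultures, SD, n = 2), Chst2, a sulfotransferase, Cyp1a1, Ahr and Snn. Cyp1a1, a cytochrome P450 gene that the aryl hydrocarbon receptor activates, was at 0.51 ± 0.263 and 5.63 ± 0.0247 FPKM, and Ahr, which encodes that receptor, at 0.741 ± 0.324 and 5.79 ± 0.359 FPKM. Those lower included Gzmb, Socs2, Thy1 and Treml2. Thy1, a surface protein of T cells, was at 79.9 ± 22 FPKM in control and 5.28 ± 0.228 in DMF cultures, a ratio of 15.2. The limma adjusted p of the 10 genes taken by the rule lay between 0.128 and 0.196. With the gene length trend removed, a setting chosen after the data were seen, Gzmb, Socs3 and Thy1 passed at an adjusted p of 0.0422. Over 18 alternatives the limma adjusted p of Gzmb ran from 4.51e-24, with the replicate number as a block, to 0.415, with no filter on low values. The labels do not say that a replicate number marks a shared animal or day.

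STAT-induced feedback genes are switched on by cytokine receptors through STAT transcription factors and many of them damp that signal. The list of 12 fell (median -1.26, camera adjusted p = 1.46e-07; adjusted p = 0.216 with an estimated correlation), and 10 of its members lay below both controls in both DMF libraries. Adjusted over the list alone, Socs1, Socs2, Socs3, Cish, Bcl3, Pim1 and Pim2 fell, and none passed over all genes. Socs3 (GRCm38 chromosome 11, 117966079 to 117970047) was at 77.2 ± 12.9 FPKM in control and 9.67 ± 0.0219 in DMF cultures (SD, n = 2). Cish was at 35.1 ± 3.01 and 8.26 ± 0.314 FPKM, and Socs2 at 9.49 ± 0.658 and 0.576 ± 0.0761 FPKM. Bcl3, an NF-kB cofactor, was at 68.9 ± 10.5 and 16.3 ± 2.58 FPKM, while Stat3 differed by 0.09.

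The list of naive T cell genes fell (median -0.90, camera adjusted p = 9.25e-06; adjusted p = 0.216 with an estimated correlation). Without control replicate 1 its median was -1.02 with an adjusted p of 0.1 (2.81e-08 to 0.1 over 17 alternatives). S1pr1 (GRCm38 chromosome 3, 115710433 to 115715072), the receptor by which T cells leave lymph nodes, was at 37.5 ± 2.78 FPKM in control and 7.41 ± 1.35 in DMF cultures (SD, n = 2), and Il7r at 4.57 ± 0.605 and 0.342 ± 0.013 FPKM. Of the 16 members, 11 lay below both controls in both DMF libraries and 2 above, and 9 fell adjusted over the list alone.

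Th1 genes, which mark interferon-gamma-producing helper T cells, fell as a list (median -1.14 over 15 tested, camera adjusted p = 2.61e-07; adjusted p = 0.216 with an estimated correlation). All 15 had negative log2 fold changes, 12 lay below both controls in both DMF libraries, and 8 fell adjusted over the list alone. Nkg7, a cytotoxic granule gene, was at 35.8 ± 20.7 FPKM in control and 5.33 ± 0.176 in DMF cultures (SD, n = 2). Stat4, which carries the interleukin 12 signal, was at 7.86 ± 0.0178 and 3.2 ± 0.31 FPKM, and Runx3, a partner of T-bet, at 15.7 ± 3.22 and 6.46 ± 0.107 FPKM. Tbx21, which encodes T-bet, differed by -0.27 ± 0.21 on the log2 scale (SE). Ifng was below the filter, with 15 and 21 reads in the controls and 0 in each DMF library. CD8 T and NK cells also express Gzmb, Nkg7 and Ifng, and their tested markers were lower too, with Cd8a and Klrd1 at ratios of 23.4 and 16.1 between control and DMF cultures.

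The Treg list fell (median -0.60 over 12 tested, camera adjusted p = 0.000257; adjusted p = 0.216 with an estimated correlation), and its median was -0.337 without control replicate 2. Lrrc32, the anchor of latent TGF-beta on regulatory T cells, was at 6.23 ± 1.02 FPKM in control and 0.249 ± 0.191 in DMF cultures (SD, n = 2), and Il2ra, the high-affinity interleukin 2 receptor chain, at 155 ± 20.7 and 95.6 ± 2.02 FPKM. The Th2 list also fell (median -0.58 over 5 tested, camera adjusted p = 0.00127; adjusted p = 0.216 with an estimated correlation), with all 5 members below both controls in both DMF libraries. That median was -0.541, with an adjusted p of 0.173 (3.32e-05 to 0.173 over the alternatives), without control replicate 1. Il13 was at 2.65 ± 0.376 FPKM in control and 0.0889 ± 0.126 in DMF cultures. Th17 genes did not move as a list (median 0.06 over 6 tested, camera adjusted p = 0.727), with Ahr higher and Il17f lower in the DMF libraries, and the median was -0.109 without control replicate 2 and 0.351 without control replicate 1. The T cell activation list did not pass (median -0.20 over 19 tested, camera adjusted p = 0.332) and its median was 0.0351 without control replicate 2 and -0.354 without control replicate 1. Egr2, a transcription factor induced by antigen receptor signals, was at 16.5 ± 1.08 FPKM in control and 36.8 ± 0.891 in DMF cultures, and Nr4a1, another gene induced by that signal, at 43.8 ± 5.38 and 14.1 ± 0.701 FPKM.

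Type I interferon response genes fell as a list (median -0.56 over 21 tested, camera adjusted p = 0.000786; adjusted p = 0.216 with an estimated correlation), and 13 of them lay below both controls in both DMF libraries. Its median was -0.729, with an adjusted p of 0.1 (2.63e-05 to 0.1 over 17 alternatives), without control replicate 1. Irf7, the regulator of interferon genes, was at 8.44 ± 3.58 FPKM in control and 1.97 ± 0.322 in DMF cultures (SD, n = 2), and Usp18, a brake on interferon signalling, at 5.21 ± 0.0189 and 1.8 ± 0.313 FPKM. Members in the other direction included Rsad2, Ifit1 and Ifit3, with log2 fold changes of 0.73, 0.31 and 0.36.

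Cell cycle genes rose as a list (median 0.33 over 28 tested, camera adjusted p = 0.000295; adjusted p = 0.36 with an estimated correlation), with 16 members above both controls in both DMF libraries and 0 below. Without control replicate 1 the median was 0.291 with an adjusted p of 0.1 (2.32e-09 to 0.1 over 17 alternatives). Bub1, a mitotic checkpoint kinase, was at 4.71 ± 0.946 FPKM in control and 8.22 ± 0.52 in DMF cultures (SD, n = 2), and Mcm4, a subunit of the replicative helicase, at 47.6 ± 6.82 and 74.2 ± 1.55 FPKM. Integrated stress response genes, which answer amino acid shortage and other stress through ATF4, rose as a list (median 0.32 over 18 tested, camera adjusted p = 0.0018; adjusted p = 0.56 with an estimated correlation). The median was 0.106, with an adjusted p of 0.401 (1.17e-08 to 0.401 over 17 alternatives), without control replicate 1. Chac1, which degrades glutathione, was at 1.77 ± 0.41 FPKM in control and 4.43 ± 0.218 in DMF cultures. Slc7a5, an amino acid transporter, was at 31.4 ± 5.88 and 63.8 ± 1.32 FPKM.

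Oxidative phosphorylation genes fell as a list (median -0.47 over 22 tested, camera adjusted p = 0.00127; adjusted p = 0.636 with an estimated correlation), but the median was -0.0594 without control replicate 2 and -0.886 without control replicate 1, and under quantile normalization it was -0.159 with an adjusted p of 0.0576 (1.11e-05 to 0.0576 over 17 alternatives). Cox4i1, a subunit of cytochrome c oxidase, was at 270 ± 158 FPKM in control and 131 ± 3.92 in DMF cultures (SD, n = 2). Glycolysis genes did not pass (median -0.20 over 20 tested, camera adjusted p = 0.118), and the median was -0.165 without control replicate 2. Among the alternatives that kept every library, they passed in 2, both chosen after the data were seen. These were removal of the gene length trend (median -0.27, camera adjusted p = 0.0104) and library quality weights (camera adjusted p = 0.0418). Slc16a3, a lactate exporter, was at 55.6 ± 11.6 and 30.5 ± 0.309 FPKM. Gapdh, whose reads can be shared with pseudogenes, was at 58.2 FPKM in DMF replicate 1 and at 12.7, 13.8 and 14.8 FPKM in the other libraries. Heat shock genes (median 0.03 over 15 tested, camera adjusted p = 0.653), p53 targets (-0.10 over 16, 0.627), cholesterol synthesis genes (0.12 over 20, 0.332) and NF-kB targets (-0.17 over 16, 0.615) did not pass. The NF-kB median was -0.298 without control replicate 1 and -0.032 without control replicate 2, and the p53 median -0.0605 without control replicate 2. Without control replicate 1 the heat shock median was -0.0766, and without control replicate 2 cholesterol synthesis passed (median 0.0997, adjusted p = 0.0496; 0.0496 to 0.595 over 17 alternatives). Hspa1b, an inducible chaperone with a near-identical copy in Hspa1a, was at 23.1 ± 2.26 FPKM in control and 8.36 ± 0.223 in DMF cultures. Cd83, an NF-kB target and activation marker, was at 10.5 ± 2.04 and 20.5 ± 1.41 FPKM.

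Of the markers of other cell types, B cell markers rose as a list (median 0.77 over 10 tested, camera adjusted p = 0.000414; adjusted p = 0.216 with an estimated correlation), and without control replicate 1 the median was 0.65 with an adjusted p of 0.108 (1.24e-05 to 0.108 over the alternatives). Pax5, a transcription factor that sets B cell identity, was at 0.362 ± 0.145 FPKM in control and 1.65 ± 0.137 in DMF cultures (SD, n = 2), while Ighm was at 71.6 and 107 FPKM in the controls and 62.7 and 62.4 FPKM in the DMF libraries. Of the CD8 T and NK cell markers 3 could be tested, too few for a list test. All 3 lay below both controls in both DMF libraries, with Cd8a at 1.92 ± 0.351 FPKM in control and 0.082 ± 0.0327 in DMF cultures and Klrd1 at 7.07 ± 2.52 and 0.44 ± 0.442 FPKM. T cell identity markers fell as a list (median -0.36 over 13 tested, camera adjusted p = 0.0138; adjusted p = 0.6 with an estimated correlation), with Cd2 at 190 ± 78.2 and 58.7 ± 1.08 FPKM and Cd4 at 128 and 105 FPKM in the controls and 103 and 100 FPKM in the DMF libraries. That median was -0.909 without control replicate 1, -0.124 without control replicate 2 and 0.106 under quantile normalization, and the adjusted p was 0.0691 without DMF replicate 1 and 0.0903 without DMF replicate 2 (0.00145 to 0.791 over 17 alternatives). Myeloid and dendritic cell markers did not pass (median -0.12 over 8 tested, camera adjusted p = 0.693), with Cd14 lower and H2-Aa higher in the DMF libraries, and the median was -0.539 without control replicate 1, 0.167 without control replicate 2, -0.245 without DMF replicate 1 and 0.00133 without DMF replicate 2. Of the erythroid and platelet markers only Itga2b was tested, at 0.919 ± 0.0411 FPKM in control and 1.32 ± 0.157 in DMF cultures.

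**Figure D3:**
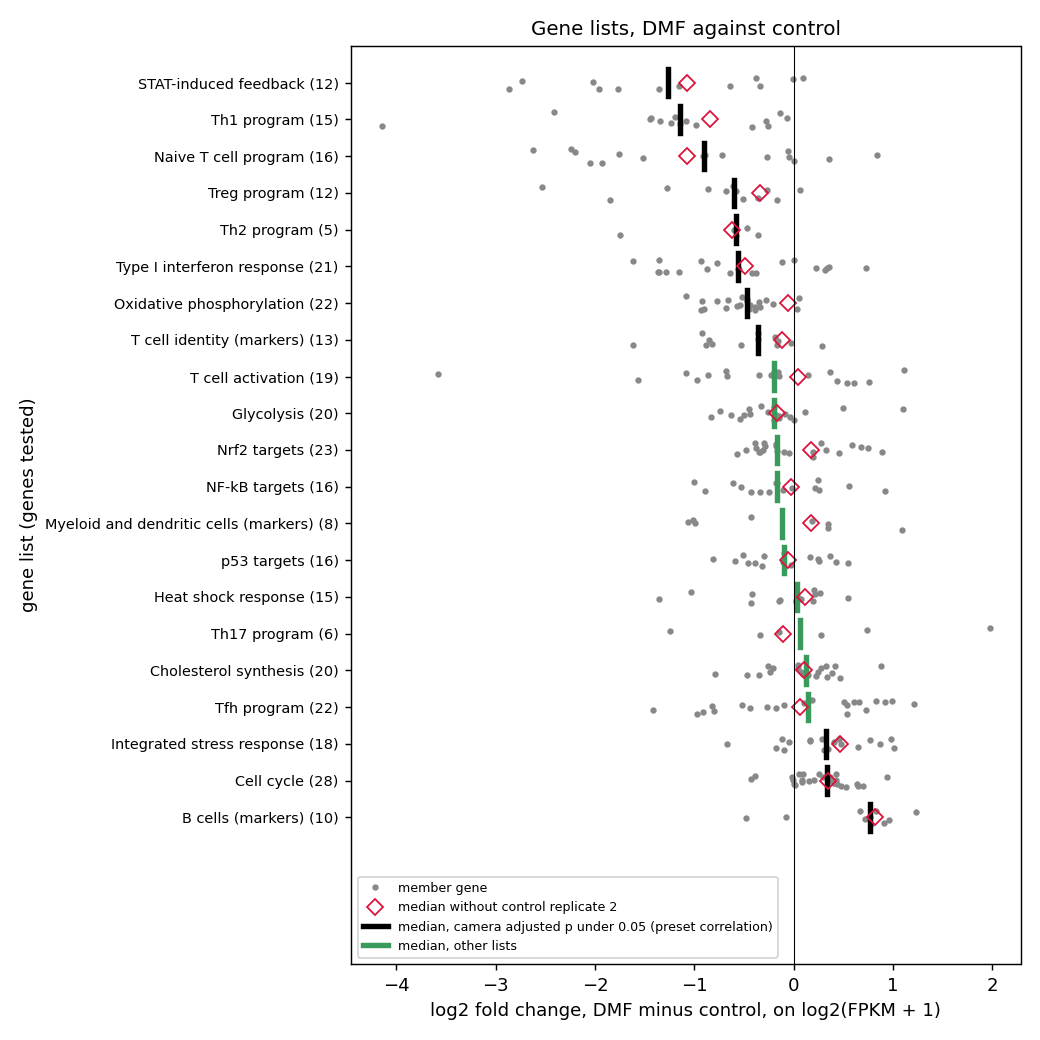
Log2 fold changes (x axis, DMF minus control on log2(FPKM + 1)) of the members of the 21 tested gene lists (y axis, number of genes tested in brackets), with a thick bar at each list's median, black where camera with the preset correlation passed, and a diamond at the median without control replicate 2. The STAT-induced feedback list has the lowest median, -1.26, and the B cell list the highest, 0.77.

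In all, 11 of the 21 lists passed with camera's preset correlation, 8 lower and 3 higher in the DMF libraries, and 0 passed with an estimated correlation, where 3 had an unadjusted p under 0.05. limma's fry, which asks only whether a list's own genes move, called 9 lists, and 13 in its mixed form. In its directional form the cell cycle, integrated stress response, oxidative phosphorylation and T cell identity lists did not pass (adjusted p = 0.105, 0.228, 0.382 and 0.238). The T cell activation and cholesterol synthesis lists, which camera did not call, passed in that form (fry adjusted p = 0.0274 each). With 2 libraries against 2, an exact permutation test cannot go below 0.333 (two-sided). The p-values of single genes and of fry therefore rest on limma's spread shared across genes. With the preset correlation of 0.01, camera sets a list's genes against other genes as nearly independent units. Its small p-values therefore do not measure the spread between libraries alone.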

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

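Removing the gene length or GC trend, library quality weights, voom and camera without a variance trend were chosen after the data were seen. The quality weights came out at 0.2 for both controls and 4.98 for both DMF libraries. They therefore did not set control replicate 2 below control replicate 1. limma called 0 genes in the main setting and under 12 alternatives, with adjusted p at their lowest from 0.0519 (quantile normalization) to 0.415 (no filter), and 630 to 2125 genes at an unadjusted p under 0.05. It called 3 with the gene length trend removed, all lower in the DMF libraries. Leaving out each library gave 6 to 7420 calls: 7420 without control replicate 1, 1007 without control replicate 2 (337 higher, 670 lower), 8 without DMF replicate 1 and 6 without DMF replicate 2, where the lone library left is assumed to vary like the other group's pair. A simulation without control replicate 2 made 91 false calls. With the replicate number as a block, 552 genes were called (203 higher, 349 lower). The labels do not say that a number marks a shared animal or day. Deviations of same-numbered libraries correlated at -0.023 across genes. The departure of control replicate 2 could hide a shared effect, so this value does not decide whether the numbers pair the samples. The planned edgeR and DESeq2 fits on recovered reads were not run, and voom on those reads took their place.

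The count of called lists, 11, was 9 to 14 under the other settings, except 5 without control replicate 1 and 0 with an estimated correlation; over the left-out libraries it ran from 5 to 14. The STAT-induced feedback, Th1 and Treg lists kept direction and threshold in all 17 alternatives that refit the genes, with medians from -1.44 to -0.93, -1.27 to -0.84 and -0.76 to -0.28. Without control replicate 1, 6 lists no longer passed (Th2, naive, cell cycle, integrated stress, interferon and B cell lists), and with the replicate block the T cell identity list did not. With a mean FPKM of at least 5 the Th2, Th17 and B cell lists held too few genes for a test. Negative medians numbered 15 over all 23 lists, 2 of them untested, and stayed between 10 and 16.

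Reversed medians were, under quantile normalization, Nrf2 targets at 0.212, glycolysis at 0.152, p53 targets at 0.0346, NF-kB targets at 0.119 and T cell identity at 0.106. Over the left-out libraries medians ran from -0.27 (without control replicate 1) to 0.167 (without control replicate 2) for Nrf2 targets, from 0.351 to -0.109 for Th17, from -0.354 to 0.0351 for T cell activation and from -0.539 to 0.167 for myeloid markers, and from -0.0766 to 0.109 for heat shock. With the length trend removed they were Nrf2 targets at 0.0274, heat shock at -0.00195 and myeloid markers at 0.24. Myeloid markers were at 0.0286 and Th17 at -0.152 with no filter, and myeloid markers at 0.341 with a mean FPKM of at least 5 and 0.00133 without DMF replicate 2. Of single genes, the log2 fold change of Nfe2l2, -0.01, was 0.022 with trimmed mean scaling, 0.0259 with quantile normalization and 0.0535 with the length trend removed, and ran from -0.0595 without control replicate 2 to 0.0449 without control replicate 1 over the left-out libraries (0.0322 without DMF replicate 2). Keap1 was at 0.0577 with the GC trend removed and Hspa8 at 0.214 with quantile normalization. The cause was not tested. Of 100 named genes in the test, 38 passed with the replicate block and 3 with the length trend removed. Over all 12166 tested genes, 552 and 3 passed in these settings. Most named genes were taken for the smallest p in these same libraries, so a higher share among them was built in. Nqo1 and Prdm1, below the filter, moved by more than their spread with pseudocounts of 0.1 and 0.5 and with voom. Depth limits genes with few reads, such as Ifng and Nqo1.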

Other observations

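Guanylate-binding and immunity-related GTPases, which interferon-gamma induces, and aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, were examined as lists chosen after the data were seen. The 14 tested genes of the GTPase list, Irf1 included, fell as a list (median -0.80, camera adjusted p = 9.64e-09; adjusted p = 0.0729 with an estimated correlation), and 13 of them lay below both controls in both DMF libraries. Gbp2 was at 115 ± 8.85 FPKM in control and 45.1 ± 3.51 in DMF cultures (SD, n = 2), and Iigp1 at 3.5 ± 0.565 and 1.01 ± 0.0632 FPKM. Without control replicate 2 the median was -0.99. The 14 synthetase genes rose as a list (median 0.16, camera adjusted p = 0.0425, and 0.406 with an estimated correlation), with 9 above both controls in both DMF libraries and 1 below. For lists chosen after the data were seen, camera adjusted p cover only those 3 lists. The synthetase list therefore met a lighter correction than the 21 fixed lists.

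Leaving out each library was planned, but its use as a test of these patterns, removal of the length trend from gene lists, and the interferon-gamma and aryl hydrocarbon receptor tests were chosen only after the results were seen. The departure of control replicate 2 was weighed against gene length, GC content and ribosomal protein genes. The SD of the log2 difference between the controls was 0.74, against 0.32 between the DMF libraries. It was 0.64 with the gene length trend removed and 0.72 with the GC trend removed, both above the bound of 0.47 set beforehand, which argues against each as the whole cause. Without the 94 ribosomal protein genes it was 0.74, also above the bound. Reads taken by these genes would shift all other genes evenly, which an SD does not register, so that test cannot decide. Gene length accounted for 26.8% of the variance between the controls and 0.031% between the DMF libraries, so it may be part of the cause. No biological explanation was tested, and a difference in library preparation stays open.

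The lower STAT-induced feedback, naive T cell and Th1 genes (median -1.14 over 43 genes) were weighed against control replicate 2 and gene length. The median was -1.04 without control replicate 2 and -1.03 with the length trend removed, which argues against either as the whole cause. The 3 splits of the 4 libraries into 2 and 2 are too few for a share under 0.05. The real split called 11 lists and the highest other split 2, and counting the real one, 1 of the 3 splits called as many. The 3 tested CD8 T and NK markers were lower too (median -1.43), so fewer such cells in DMF cultures stays open for the Th1 genes they share.

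The higher B cell markers were weighed against a larger share of B cells and control replicate 2. The list's median was 0.82 without control replicate 2, which argues against that library as the whole cause. Igkc, the light chain gene that B cells and plasma cells express most, differed by -0.13 on the log2 scale, at 32.1 and 106 FPKM in the controls and 53.7 and 53.3 in the DMF libraries, so the groups overlapped and the test left more B cells and other sources open. Ighm, another abundant B cell transcript, was lower in both DMF libraries than in both controls. Reads of immunoglobulin variable genes went the other way, at 36.5 and 32 CPM (counts scaled to library size) in the controls and 43.4 and 41.6 CPM in the DMF libraries. The labels name naive CD4+ T cells and no sort or gate, and Bcl6, Cxcr5, Pou2af1 and Cd83 of the other lists are also expressed by B cells.

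A candidate explanation of the lower interferon-inducible genes is a weaker interferon-gamma response in DMF cultures. The GTPase median of -0.80 lay in that direction, but the list was chosen once other interferon genes and Ifng had been seen lower, so it is no independent test. Several of its genes also answer type I interferon, which the test does not separate. The higher Ahr and Cyp1a1 may reflect more aryl hydrocarbon receptor activity. Of the other target genes 2 could be tested, with a median of 0.50 (camera adjusted p = 0.0649; adjusted p = 0.406 with an estimated correlation), too few to decide. Of these 2, only Tiparp lay above both controls in both DMF libraries, at 3.54 ± 0.373 FPKM in control and 7.62 ± 0.419 in DMF cultures (SD, n = 2). For the other tested gene the groups overlapped. Cyp1b1, below the filter, was at 0.0805 ± 0.00494 and 0.865 ± 0.0474 FPKM.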
